A study of Homo sapiens with 47 samples.

How the data were processed

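RNA of MCF7 cells was measured on 12 expression arrays in 4 groups of 3. Per the labels, the authors processed them with RMA, of which no version is given. RMA corrects for background, applies quantile normalization between arrays and summarises the probes of a probe set, and the deposited values are log2 signals. Whether all 12 arrays were normalized together is not stated. Each probe set stands for a RefSeq transcript, and the source of this regrouping of probes is not stated. The table has 23597 probe sets, 62 of them controls. Array medians ran from 4.68 to 4.73 and values from 1.42 to 13.5. The 35 tiling array samples were not analysed here.

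Transcripts were matched to gene symbols with a table of RefSeq genes of GRCh38.p14. Of 23535 transcript probe sets, 19935 matched 1 symbol and 3600 none. Names were taken from this table but no coordinates, since the array's own genome build is not named. Where several probe sets carried a symbol (2586 genes), the one with the highest mean over the 12 arrays stood for the gene. For 96 genes the values equal those of another symbol. This left 15916 named genes and 3600 unnamed features, 19516 in all. Unnamed features were tested and enter the adjustment but not the counts, in which they number 71 higher and 79 lower at 3 h of EGF, 214 and 262 at 12 h, 519 and 696 for the arrays labelled ICI and EGF against EGF 3 h, 531 and 670 for the same against control, and 119 and 79 for 12 h against 3 h.

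Groups were compared with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) on the deposited log2 values, with 1 mean per group over the 12 arrays, 8 residual degrees of freedom, two-sided moderated tests, and Benjamini-Hochberg adjustment over all 19516 features at an adjusted p under 0.05. The 5 comparisons were each EGF time against control, 12 h against 3 h, and the arrays labelled ICI and EGF against EGF 3 h and against control. The 4 groups shared 1 estimate of the spread for each feature. The median SD across features was 0.111 on the arrays labelled ICI and EGF, 0.091 in control, 0.078 at 3 h of EGF and 0.081 at 12 h. Standard errors and p-values may therefore be too small for comparisons with the arrays labelled ICI and EGF, and too large for the others. No replicate term was planned or used. Arrays of the same number, as seen later, did not resemble each other across groups: deviations from the group means correlated with r between -0.247 and 0.153 over 18 pairs, with a median of -0.025. The design, the comparisons, the gene lists and the alternatives were chosen before the data were examined, except where stated.

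The 21 gene lists cover immediate early genes, MAP kinase feedback, EGF ligands and receptors, genes induced and repressed by estrogen, G1/S and replication, G2/M and mitosis, ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, NF-κB targets, invasion and matrix, luminal identity, p53 targets, ATF4 and the unfolded protein response, interferon response, FOXO and growth arrest, housekeeping, and markers of basal cells, of fibroblasts and of immune and endothelial cells. They were written from general knowledge, and some genes are in more than 1 list. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 21 lists within a comparison, then with an estimated correlation and with fry, which asks whether a list's genes move 1 way and does not compare them with other genes. Members are counted over all features and also adjusted over the list alone.

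Genes to be named were chosen by rule. They are the 8 largest rises and 8 largest falls in a comparison (4 and 4 for 12 h against 3 h) among called genes whose arrays do not overlap between groups, which chance gives for 10% of genes, up to 4 members of each list called by camera and up to 2 of the others, and a fixed panel of 12 genes. The text gives a selection of the genes this rule names.

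How much of the EGF response remained with fulvestrant was set beside 100 simulations in which it changed nothing, since both comparisons share the EGF 3 h arrays, and beside 100 in which the called differences with fulvestrant were given to other genes of like mean expression and spread, which were added after seeing the data. The overlap of the EGF time points was set beside 100 simulations of unchanged groups. Single measures of RNA quality were compared by an exact permutation test over 220 splits. Shares were compared by Fisher's exact test. The limma test was tested on simulated data of the same size, where 200 features were changed. It recovered 78 of 100 changes of 0.5 and 99 of 100 changes of 1 (log2), with 11 false calls among 188.

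The alternatives were a replicate block, a variance trend with a robust fit, leaving out the 40% dimmest features, all probe sets as separate features, the mean of a gene's probe sets, quantile normalization, centring arrays on their medians, only the 6 arrays of the groups compared, and each array left out in turn. An alternative without the arrays labelled ICI and EGF was added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.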

Results

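Transcript levels were measured on 12 expression arrays of RNA from MCF7 cells, a human breast cancer line that carries estrogen receptor α (ERα, encoded by ESR1) and grows in response to estrogen. The arrays formed 4 groups of 3. Control cells received no epidermal growth factor (EGF), a second group had EGF for 3 h, another had it for 12 h, and the last was given fulvestrant (ICI in the labels) for 3 h and then EGF for 3 h. Fulvestrant is an ERα antagonist that brings about degradation of the receptor. The labels give no time for the control cells, and no group received fulvestrant alone. The other 35 samples of the series, taken 90 min after EGF, are tiling arrays of ERα-bound chromatin (21) and of input (14), and they were not analysed here. Values are log2 RMA signals, differences are given on the log2 scale with the standard error (SE) of the limma fit, and group means are given with the SD over n = 3 arrays. With 3 arrays a group, the number of arrays limits the precision, and a p-value measures only the spread between arrays, since the labels do not say whether they came from separate cultures.

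Arrays of a group resembled each other closely. Across transcripts, Pearson's r was 0.995 to 0.997 between arrays of the same group without fulvestrant and 0.993 to 0.994 among the arrays labelled ICI and EGF. Between groups it was 0.988 to 0.994 where neither array was labelled ICI and EGF, and 0.973 to 0.983 where 1 of them was. The first principal component, with 55.3% of the variance, set the 3 arrays labelled ICI and EGF apart from the other 9. The same 3 arrays differed in signs of RNA quality. The 3′ probe set of ACTB exceeded its 5′ probe set by 1.76 ± 0.14 on them, against 0.81 ± 0.03 in control, 0.68 ± 0.03 after 3 h of EGF and 0.71 ± 0.09 after 12 h. For GAPDH the gap was 1.10 ± 0.08 against 0.33 ± 0.04, 0.34 ± 0.01 and 0.37 ± 0.06. The 3′ probe sets differed from the other 9 arrays by -0.01 (ACTB) and 0.02 (GAPDH), and the 5′ probe sets by -1.04 and -0.73. In an exact two-sided permutation test over the 220 splits of the arrays, both 5′ differences had p = 0.00455, the smallest these splits can give, and the 3′ differences had p = 0.845 and p = 0.336.

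**Figure D1:**
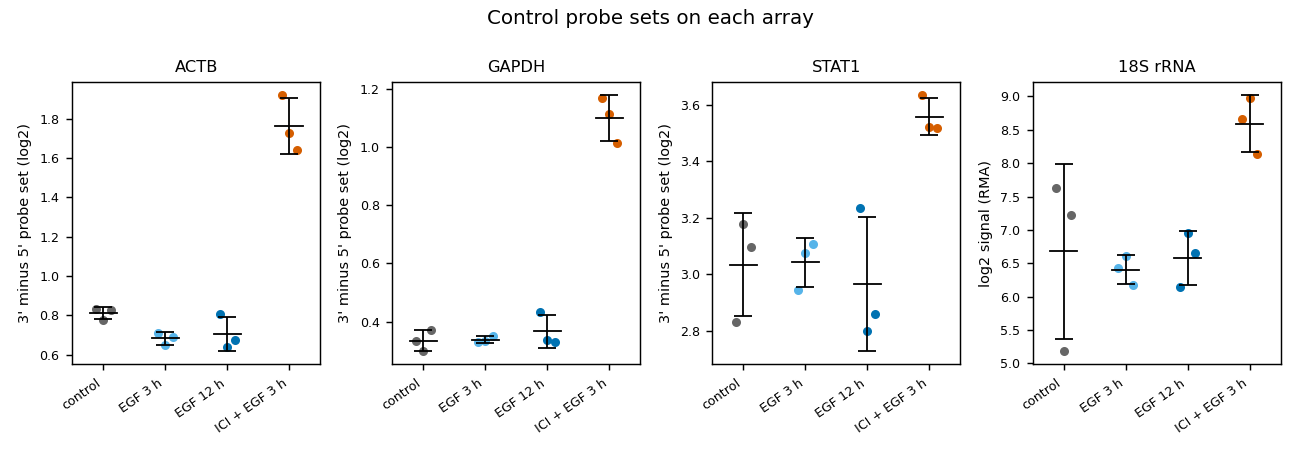
Control probe sets on each of the 12 arrays. The first 3 panels give the 3′ minus the 5′ probe set of ACTB, GAPDH and STAT1 (log2), the last the signal of the 18S ribosomal RNA probe set (log2); points are arrays, and bars are the mean and SD of a group (n = 3). The arrays labelled ICI and EGF lie between 1.64 and 1.92 for ACTB, and the other 9 between 0.64 and 0.83.

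EGF for 3 h against control asked which transcripts respond early to the growth factor. Transcripts of signalling feedback, ribosome assembly and invasion were higher after EGF, and those of growth arrest, of the p53 response and of genes that estrogen represses were lower. The largest rise was that of F2RL1, a protease-activated receptor, from 4.36 ± 0.16 to 7.15 ± 0.09, or 6.91-fold (adjusted p = 3.1e-09). The death receptor TNFRSF21 rose by 2.16 ± 0.07, PHLDA2 by 2.11 ± 0.08, and AREG, which encodes the EGF receptor ligand amphiregulin, by at least 2.08 ± 0.12, as its control value (2.80) was no higher than that of the fibroblast marker COL1A2 (3.05). ARAP2 (1.96 ± 0.12), PHLDA1 (1.95 ± 0.07) and ZNF365 (1.87 ± 0.13) were also among the 8 largest rises. ID2, an inhibitor of helix-loop-helix transcription factors, showed the largest fall, from 8.72 ± 0.02 to 7.53 ± 0.20, or 2.28-fold (adjusted p = 1.45e-05). It was followed by the lipid phosphatase MTMR4 (-1.07 ± 0.08), the polysialyltransferase ST8SIA4 (-1.06 ± 0.10), PRR15L (-1.02 ± 0.09), the protocadherin PCDH10 (-0.98 ± 0.09), the surface antigen PSCA (-0.94 ± 0.11) and ARMCX1 (-0.89 ± 0.09). Other probe sets of ST8SIA4 and PCDH10 did not pass the test. KLRG2 (-0.89 ± 0.19) was the last of the 8 largest falls, and without control replicate 1 its adjusted p was 0.0608.

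Of the 29 immediate early genes, the transcription factors and regulators that growth factors induce within an hour, 10 rose at 3 h of EGF, 2 fell and 17 did not pass the test. Adjusted over the list alone, 16 rose and 3 fell. EGR1 rose by 1.54 ± 0.08, FOSL1 by 0.96 ± 0.13, TRIB1 by 0.86 ± 0.07 and KLF4 by 0.85 ± 0.06, and the list's median was 0.22 (camera adjusted p = 2.59e-08). Among 24 feedback regulators of the MAP kinase pathway, 10 rose and 14 did not pass (12 higher and 2 lower adjusted over the list alone). They included the phosphatase DUSP5 (1.09 ± 0.09) and the EGF receptor inhibitor ERRFI1 (0.99 ± 0.07), with a list median of 0.19 (camera adjusted p = 9.75e-08). Of 24 genes of ribosome biogenesis, 12 rose and 12 did not pass (16 higher adjusted over the list alone). The RNA helicase DDX21 rose by 0.79 ± 0.07 and the nucleolar proteins NOP16 and NOP2 by 0.77 ± 0.07 and 0.52 ± 0.06 (list median 0.31, camera adjusted p = 9.38e-12). Of 25 genes of invasion and matrix, 5 rose and 20 did not pass (9 higher adjusted over the list alone), among them the integrins ITGA2 (0.85 ± 0.13) and ITGA6 (0.75 ± 0.12), with a list median of 0.17 (camera adjusted p = 2.29e-06). In the list of 8 basal epithelial markers, FOXC1 (0.66 ± 0.12) and the caveola protein CAV1 (0.41 ± 0.07) rose and 6 did not pass (4 higher adjusted over the list alone, list median 0.19, camera adjusted p = 0.000449).

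Of 10 genes known to be repressed by estrogen, 6 fell at 3 h of EGF and 4 did not pass (7 lower adjusted over the list alone). Next to PSCA, the pro-apoptotic gene BIK fell by 0.74 ± 0.09 and the cyclin CCNG2, linked to cell cycle arrest, by 0.69 ± 0.08, and the list median was -0.59 (camera adjusted p = 1.88e-09). Of 36 genes known to be induced by estrogen, 4 rose, 3 fell and 29 did not pass (5 higher and 7 lower adjusted over the list alone). FHL2, a LIM-domain protein, rose by 1.63 ± 0.09 and the transcription factor MYB by 0.76 ± 0.10, and as a list they did not differ from other genes (median -0.07, mean 0.005, camera adjusted p = 0.481). Of 22 p53 target genes, 8 fell and 14 did not pass (2 higher and 10 lower adjusted over the list alone). BTG2 fell by 0.57 ± 0.07, TP53INP1 by 0.54 ± 0.07 and CCNG1 by 0.47 ± 0.07 (list median -0.17, camera adjusted p = 3.85e-05). In the list of 21 FOXO targets and growth arrest genes, 9 fell, 2 rose and 10 did not pass (11 lower and 2 higher adjusted over the list alone). KLHL24 fell by 0.71 ± 0.07 and the glucocorticoid-induced gene TSC22D3 by 0.68 ± 0.07 (list median -0.20, camera adjusted p = 3.46e-06). The 8 lists called so far kept their call with an estimated correlation between genes. The 25 genes of G2/M and mitosis had 10 lower, 1 higher and 14 that did not pass (14 lower and 1 higher adjusted over the list alone), with HMMR lower by a log2 difference of -0.48 ± 0.09. Their median was -0.20 (camera adjusted p = 5.5e-07, and adjusted p = 0.0951 with an estimated correlation).

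Of 29 genes of G1/S and DNA replication at 3 h of EGF, 2 fell, 1 rose and 26 did not pass (2 lower and 1 higher adjusted over the list alone), with a median of -0.12. The camera adjusted p of this list was 0.0427, but 0.438 with an estimated correlation, 0.102 without control replicate 2, 0.0541 without EGF 3 h replicate 2, 0.0994 without EGF 3 h replicate 3, 0.175 without the dimmest features, 0.0856 after quantile normalization and 0.0627 by fry, so that the call rested on those choices. Lists that camera did not call were 12 EGF ligands and receptors (2 higher, 1 lower), 22 genes of cholesterol synthesis (2 higher, 1 lower), 17 of glycolysis and hypoxia (1 higher, 3 lower), 20 NF-κB targets (2 higher), 16 luminal genes (2 higher, 1 lower), 16 ATF4 and unfolded protein response genes (2 higher, 2 lower) and 13 interferon-response genes (1 lower). Examples from them were the receptor ERBB3 (-0.43 ± 0.06), the oxygen sensor EGLN3 (1.53 ± 0.14), the cytokine LIF (0.91 ± 0.10), the transcription factors ELF3 (-0.51 ± 0.06) and XBP1 (0.39 ± 0.08), the amino acid transporter SLC7A5 (0.61 ± 0.07) and IRF9 (-0.34 ± 0.07). By limma, 0 of 12 housekeeping genes, 0 of 9 fibroblast markers and 0 of 9 immune and endothelial markers passed, and at an unadjusted p under 0.05 the counts were 3, 0 and 0.

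By limma, 607 genes were higher and 601 lower at 3 h of EGF than in control, of 15916 named genes and at an adjusted p under 0.05. Of the rises 49 were at least 2-fold, and of the falls 4. Both counts depended on single arrays. Without EGF 3 h replicate 2, 404 genes were higher and 310 lower. The number lower was 309 without EGF 3 h replicate 1, 327 without control replicate 1 and 321 without control replicate 2.

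EGF for 12 h against control asked for the later response. Genes of DNA replication, of ribosome assembly and of the immediate early response were higher, and genes of mitosis and of growth arrest were lower. AREG rose from 2.80 ± 0.20 to 6.61 ± 0.09, or at least 14.1-fold (adjusted p = 9.69e-10), since its control value was level with that of the fibroblast marker FAP (2.79) and so perhaps not above background. The secreted protease KLK6 rose by 2.96 ± 0.12, EGR1 by 2.87 ± 0.08, the neuropeptide GAL by 2.65 ± 0.14, PHLDA2 by 2.60 ± 0.08, the membrane protein MALL by 2.51 ± 0.07 and the oxytocin receptor OXTR by 2.38 ± 0.18. The largest fall was in AKR1C3, a steroid-metabolising reductase, from 7.79 ± 0.04 to 6.28 ± 0.22, or 2.84-fold (adjusted p = 6.79e-07). ID2 fell by 1.34 ± 0.10, the membrane estrogen receptor GPER1 by 1.33 ± 0.07, TARP by 1.24 ± 0.23, the potassium channel KCNJ8 by 1.19 ± 0.07 and PCDH10 by 1.17 ± 0.09. The last of the 8 largest falls were in the neuropeptide receptor NPY1R, which fell by 1.15 ± 0.15, and in GREB1, a growth regulator induced by estrogen, which fell by 1.10 ± 0.13. Other probe sets of PCDH10 and GREB1 did not pass the test.

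Of 29 genes of G1/S and DNA replication, 26 rose at 12 h of EGF and 3 did not pass (27 higher adjusted over the list alone). The replication licensing factor CDC6 rose by 1.44 ± 0.08, cyclin CCNE2 by 1.39 ± 0.13, and the replication factors GINS2 and MCM10 by 1.27 ± 0.06 and 1.15 ± 0.07. The list's median was 0.72 (camera adjusted p = 1.32e-24). Of 25 genes of G2/M and mitosis, 19 fell and 6 did not pass (21 lower adjusted over the list alone). HMMR fell by 1.08 ± 0.09, the kinesin KIF20A by 1.02 ± 0.10 and the spindle protein NUSAP1 by 0.72 ± 0.08 (list median -0.47, camera adjusted p = 1.41e-14). Of 24 genes of ribosome biogenesis, 20 rose and 4 did not pass (22 higher adjusted over the list alone), with DDX21 at 1.12 ± 0.07 and the nucleolar proteins NOP16 and NOLC1 at 1.08 ± 0.07 and 0.93 ± 0.09 (list median 0.53, camera adjusted p = 2.99e-18). Of 29 immediate early genes, 18 rose, 1 fell and 10 did not pass (20 higher and 2 lower adjusted over the list alone). EGR3 rose by 1.66 ± 0.08, FOS by 1.20 ± 0.16 and TRIB1 by 1.14 ± 0.07 (list median 0.46, camera adjusted p = 8.59e-13). The 24 MAP kinase feedback genes had 9 higher, 2 lower and 13 that did not pass (11 higher and 2 lower adjusted over the list alone), with PHLDA1 at 1.93 ± 0.07, DUSP5 at 1.65 ± 0.09, ERRFI1 at 1.60 ± 0.07 and a list median of 0.20 (camera adjusted p = 2.6e-06).

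At 12 h of EGF, 11 of 25 genes of invasion and matrix rose and 14 did not pass (13 higher adjusted over the list alone). They included ITGA2 (1.02 ± 0.13), the laminin LAMB3 (0.74 ± 0.12) and ITGA6 (0.66 ± 0.12), and the list median was 0.29 (camera adjusted p = 6.89e-06). Of 10 estrogen-repressed genes, 8 fell and 2 did not pass (8 lower adjusted over the list alone). CCNG2 fell by 0.80 ± 0.08 and the cytokine receptor IL1R1 by 0.77 ± 0.07 (list median -0.52, camera adjusted p = 2.97e-06). Of 21 FOXO and growth arrest genes, 14 fell, 2 rose and 5 did not pass (the same counts of 14 and 2 adjusted over the list alone), with TSC22D3 and the glucose-uptake inhibitor TXNIP at -0.90 ± 0.07 and -0.88 ± 0.06 (list median -0.49, camera adjusted p = 1.21e-09). All of these lists at 12 h kept their call with an estimated correlation. The 22 genes of cholesterol synthesis had 10 higher, 2 lower and 10 that did not pass (16 higher and 2 lower adjusted over the list alone). MSMO1 rose by 0.79 ± 0.09 and the LDL receptor LDLR by 0.58 ± 0.07, with a list median of 0.22 (camera adjusted p = 6.27e-06, and adjusted p = 0.0694 with an estimated correlation).

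The estrogen-induced list at 12 h of EGF had 6 higher and 10 lower of 36, with a median of -0.02 (camera adjusted p = 0.948), and 20 did not pass. The p53 targets had 5 higher, among them the stress cytokine GDF15 (0.90 ± 0.07), and 8 lower of 22, among them CCNG1 (-0.74 ± 0.07), with a camera adjusted p of 0.242. Also not called by camera were EGF ligands and receptors (2 higher, 2 lower), glycolysis and hypoxia (2 higher, 4 lower), NF-κB targets (2 higher), luminal genes (3 higher, 5 lower), ATF4 and unfolded protein response genes (5 higher, 3 lower), interferon-response genes (2 lower), housekeeping genes (3 higher) and basal markers (1 higher). ERBB3 (-0.61 ± 0.06), EGLN3 (1.83 ± 0.14), LIF (1.04 ± 0.10), the luminal transcription factor SPDEF (-0.45 ± 0.07), the chaperone cofactor SDF2L1 (0.58 ± 0.06) and the purine salvage enzyme HPRT1 (0.64 ± 0.07) were examples. By limma, 0 of 9 fibroblast markers and 0 of 9 immune and endothelial markers passed, and at an unadjusted p under 0.05 the counts were 1 and 0. At 12 h of EGF, limma called 1565 genes higher and 1608 lower than in control, 104 and 20 of them by at least 2-fold.

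**Figure D2:**
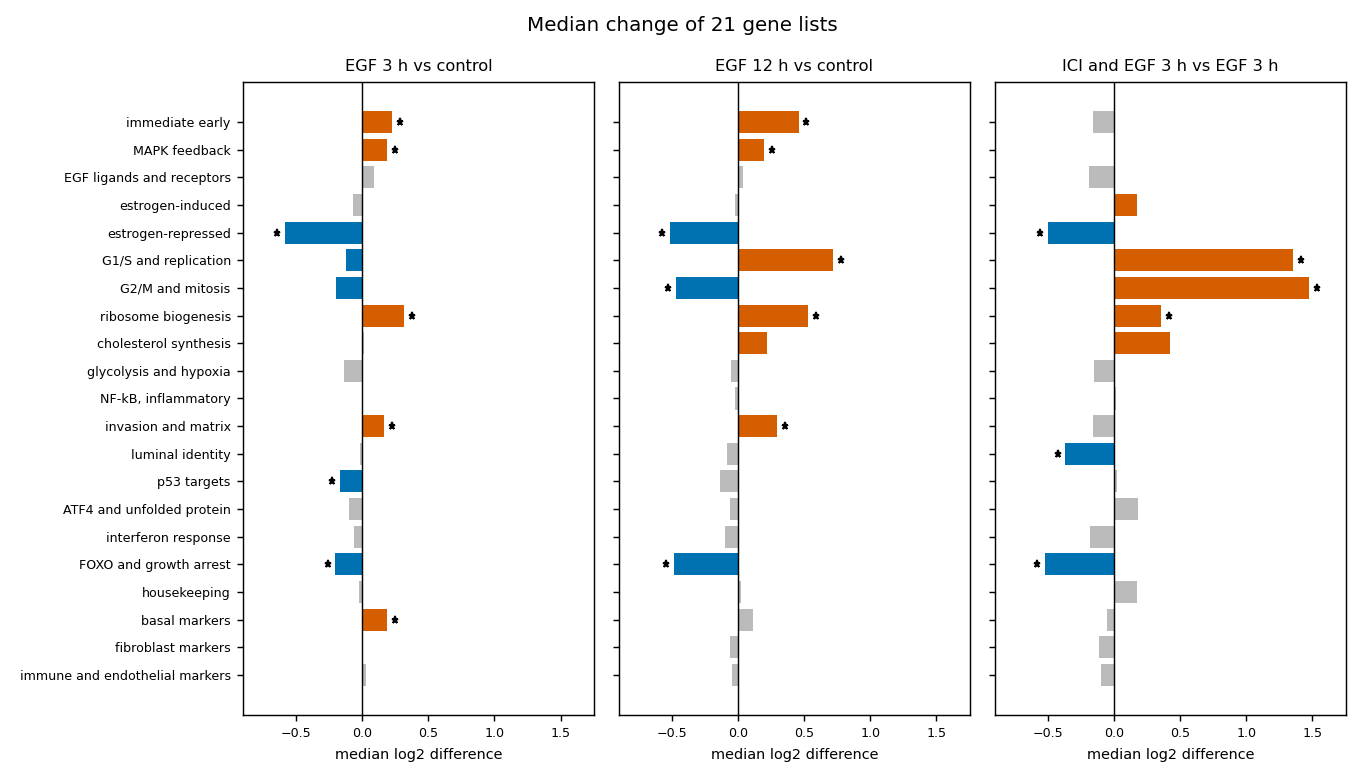
Median log2 difference of each of the 21 gene lists in 3 comparisons (horizontal axis, log2). Orange and blue bars mark lists that camera called higher or lower at an adjusted p under 0.05, grey bars the others, and a star a call that held with an estimated correlation between genes. The bar of G1/S and replication genes runs to 0.72 for EGF 12 h against control, where that of G2/M and mitosis genes runs to -0.47, and to 1.35 and 1.47 for the arrays labelled ICI and EGF against EGF 3 h.

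The difference between the EGF time points was tested directly. Replication, immediate early and ribosome biogenesis genes were higher at 12 h than at 3 h, and FOXO and growth arrest genes were lower. KLK6 was higher by 2.07 ± 0.12, the imprinted non-coding RNA H19 by 1.98 ± 0.10, AREG by 1.73 ± 0.12 and the MYC-responsive gene CDCA7 by 1.70 ± 0.11. GPER1 was lower by a log2 difference of -1.39 ± 0.07, RGCC by -1.15 ± 0.13, the cytolinker DST by -1.15 ± 0.07 and SYBU by -1.08 ± 0.08, and these were the 4 largest differences in each direction. Other probe sets of DST did not pass. Of 29 G1/S and replication genes, 26 were higher and 3 did not pass (28 higher adjusted over the list alone), with CDC6 at 1.47 ± 0.08, MCM5 at 1.21 ± 0.07 and a list median of 0.68 (camera adjusted p = 5.71e-41). Of 29 immediate early genes, 13 were higher, 2 lower and 14 did not pass (15 higher and 2 lower adjusted over the list alone), with EGR1 at 1.33 ± 0.08, EGR3 at 1.17 ± 0.08, JUNB at 0.63 ± 0.07 and a list median of 0.21 (camera adjusted p = 6.82e-07). Of 24 ribosome biogenesis genes, 10 were higher and 14 did not pass (14 higher adjusted over the list alone), with BOP1 at 0.70 ± 0.11 and a list median of 0.22 (camera adjusted p = 1.03e-09). Of 21 FOXO and growth arrest genes, 4 were lower and 17 did not pass (9 lower adjusted over the list alone), with YPEL2 at -0.61 ± 0.08 and a list median of -0.15 (camera adjusted p = 1.55e-05). These 4 calls held with an estimated correlation.

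Between 3 h and 12 h of EGF, 12 of 25 genes of G2/M and mitosis were lower and 13 did not pass (18 lower and 2 higher adjusted over the list alone), with PTTG1, the securin, at -0.57 ± 0.07. Of 22 genes of cholesterol synthesis, 10 were higher, 1 lower and 11 did not pass (12 higher and 2 lower adjusted over the list alone), with LDLR at 0.64 ± 0.07. The medians of these lists were -0.26 and 0.21, with camera adjusted p = 1.03e-09 and 1.13e-06, and with an estimated correlation each had an adjusted p = 0.072. Camera did not call the MAP kinase feedback (4 higher, 3 lower), EGF ligand and receptor (1 higher, 1 lower), estrogen-induced (3 higher, 6 lower), glycolysis (2 higher, 1 lower), NF-κB (1 higher), invasion (3 higher), luminal (1 higher, 3 lower), p53 (3 higher, 1 lower), ATF4 (2 higher, 1 lower), housekeeping (3 higher) and basal (2 lower) lists. By limma, 0 members of the estrogen-repressed, interferon-response, fibroblast and immune and endothelial lists passed, and at an unadjusted p under 0.05 these lists had 3, 1, 1 and 0. In all, 931 genes were higher and 535 lower at 12 h than at 3 h. Without 1 of the arrays EGF 3 h replicate 1, EGF 3 h replicate 2, EGF 12 h replicate 1 and EGF 12 h replicate 2, the number higher was 561, 600, 596 and 592, and the number lower 315, 321, 355 and 324. Without EGF 3 h replicate 3 the number lower was 309, and without EGF 12 h replicate 3 it was 308.

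The responses at 3 h and 12 h of EGF overlapped. Of the genes called against control, 466 were higher at both times, 421 lower at both and 13 called in opposite directions. Independent lists of these sizes would share 59.7, 60.7 and 120 genes. In 100 simulations in which neither group differed from the shared controls, the highest count was 0 for each, but few genes are called at all in such data, so that these counts do not test the overlap of called genes. The log2 differences correlated across genes with r = 0.69, against 0.50 in the simulations, and had a covariance of 0.0345 against 0.0046, a difference of 0.0299. Genes are not independent replicates, and part of the excess over independent lists may come from the shared control arrays, since 3 control arrays cannot be divided into 2 groups of at least 2. The number lower at both times was 248 without control replicate 1, 244 without control replicate 2, 244 without EGF 3 h replicate 1 and 236 without EGF 3 h replicate 2. The number in opposite directions was 4, 5 and 8 without control replicates 1, 2 and 3, was 5, 7 and 7 without EGF 3 h replicates 1, 2 and 3, and was 8, 6 and 7 without EGF 12 h replicates 1, 2 and 3.

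The arrays labelled ICI and EGF against EGF 3 h asked what pre-treatment with the ERα antagonist changes in the early EGF response. Genes of both phases of the cell cycle were higher on these arrays, and genes of growth arrest and luminal identity were lower. The largest rise was in the histone gene H4C3, from 6.32 ± 0.16 to 10.21 ± 0.03, or 14.8-fold (adjusted p = 5.02e-10). It did not stand for histone genes as a group, as the 44 replication-dependent ones measured had a median of -0.04, with 9 higher and 12 lower. CYP1B1 and CYP1A1, cytochrome P450 enzymes that metabolise estrogens and aromatic hydrocarbons, rose by 3.40 ± 0.08 and 3.16 ± 0.14. The mitotic kinase TTK rose by 2.73 ± 0.16, the kinetochore proteins CENPW and NDC80 by 2.62 ± 0.07 and 2.58 ± 0.13 and the kinesin KIF15 by 2.57 ± 0.14. SHCBP1 rose by at least 2.57 ± 0.12, as its value at 3 h of EGF (2.81) was level with that of FAP (2.78). The largest fall was in F2RL1, from 7.15 ± 0.09 to 4.88 ± 0.10, or 4.83-fold (adjusted p = 1.9e-09). RNASE4 fell by 2.19 ± 0.13, the ATP receptor P2RX4 by 1.96 ± 0.11, PSCA by 1.90 ± 0.11, OXTR by 1.83 ± 0.18, MALL by 1.82 ± 0.07, PLEKHB1 by 1.82 ± 0.08 and the transcription factor GTF2I by 1.78 ± 0.18. The 3′ to 5′ gap of ACTB was 1.76 on the arrays of this comparison labelled ICI and EGF and 0.68 at 3 h of EGF.

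In the arrays labelled ICI and EGF, 28 of 29 genes of G1/S and DNA replication were higher than at 3 h of EGF and 1 did not pass (28 higher adjusted over the list alone). GINS2 rose by 2.19 ± 0.06, MCM10 by 2.02 ± 0.07, CDC6 by 1.95 ± 0.08 and CDC45 by 1.79 ± 0.12, and the list median was 1.35 (camera adjusted p = 2.84e-24). Of 25 genes of G2/M and mitosis, 24 were higher and 1 did not pass (25 higher adjusted over the list alone). The checkpoint kinase BUB1B rose by 2.49 ± 0.09, KIF20A by 2.18 ± 0.10, the topoisomerase TOP2A by 2.04 ± 0.08 and NUSAP1 by 1.94 ± 0.08, with a list median of 1.47 (camera adjusted p = 2.84e-24). Beside both lists, the 3′ to 5′ gap was 1.76 against 0.68 at 3 h of EGF for ACTB and 1.10 against 0.34 for GAPDH. Of 24 genes of ribosome biogenesis, 14 were higher, 1 lower and 9 did not pass (14 higher and 1 lower adjusted over the list alone). NOP58 rose by 1.26 ± 0.06 and MRTO4 by 0.99 ± 0.09, and the list median was 0.35 (camera adjusted p = 1.09e-05). Of 21 FOXO and growth arrest genes, 17 were lower, 1 higher and 3 did not pass (the same counts of 17 and 1 adjusted over the list alone), with YPEL3 at -1.64 ± 0.06, CCNG2 at -1.26 ± 0.08, YPEL2 at -1.16 ± 0.08 and a list median of -0.53 (camera adjusted p = 6.2e-08). Of 16 luminal genes, 11 were lower and 5 did not pass (11 lower adjusted over the list alone), with the mucin MUC1 at -0.98 ± 0.12, SPDEF at -0.97 ± 0.07, the cadherin CDH1 at -0.88 ± 0.09 and a list median of -0.37 (camera adjusted p = 5.23e-06). The 5′ probe sets of ACTB and GAPDH were lower on the same arrays, by log2 differences from the other 9 of -1.04 and -0.73, beside the ribosome, growth arrest and luminal groups.

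Genes known to respond to estrogen also differed in the arrays labelled ICI and EGF. Of 10 estrogen-repressed genes, 7 were lower than at 3 h of EGF and 3 did not pass (7 lower adjusted over the list alone), with PSCA, CCNG2, ERBB2 (-0.65 ± 0.06) and TP53INP1 (-0.61 ± 0.07) the largest, and a list median of -0.50 (camera adjusted p = 4.34e-05). Of 36 estrogen-induced genes, 16 were higher, 5 lower and 15 did not pass (18 higher and 8 lower adjusted over the list alone). CCN5 rose by 2.10 ± 0.12, AGR3 by 1.99 ± 0.12, the carbonic anhydrase CA12 by 1.38 ± 0.06 and OLFM1 by 1.33 ± 0.08, with a list median of 0.18. The estrogen-induced list had a camera adjusted p = 0.00547, but adjusted p = 0.132 with an estimated correlation and adjusted p = 0.129 without the dimmest features. Of 22 genes of cholesterol synthesis, 14 were higher, 5 lower and 3 did not pass (15 higher and 5 lower adjusted over the list alone), with ACAT2 at 1.54 ± 0.06, MSMO1 at 1.39 ± 0.09, FDPS at 1.04 ± 0.08 and a list median of 0.42 (camera adjusted p = 0.000565, and adjusted p = 0.147 with an estimated correlation). The other calls in this comparison held with an estimated correlation. Beside each of these lists, the 3′ to 5′ gap of ACTB was 1.76 against 0.68 at 3 h of EGF.

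Camera did not call the other lists in the arrays labelled ICI and EGF against EGF 3 h, although many of their members passed. Fry, which does not compare a list with other genes, called several of them. Among these were the immediate early list, lower (fry adjusted p = 3.04e-06), and the ATF4 and housekeeping lists, higher (fry adjusted p = 8.14e-06 and 3.52e-07). Of 29 immediate early genes, 10 were lower and 3 higher, with JUNB at -1.36 ± 0.07 and FOS at -1.01 ± 0.16. The camera adjusted p of this list was 0.098, but 0.0456 with all probe sets as separate features. Of 24 MAP kinase feedback genes, 4 were lower and 1 higher, with the phosphatase DUSP10 at -0.85 ± 0.09 and the receptor EPHA2 at 0.88 ± 0.07. Among 12 EGF ligands and receptors, 5 were lower, such as ERBB3 (-0.87 ± 0.06), while AREG rose by 1.97 ± 0.12. The counts were 8 lower and 2 higher of 25 invasion genes, 6 and 5 of 22 p53 targets, 1 and 7 of 16 ATF4 and unfolded protein response genes, 7 and 5 of 17 glycolysis and hypoxia genes, 1 and 2 of 20 NF-κB targets, and 4 and 2 of 13 interferon-response genes. ITGA2 (-1.03 ± 0.13), BTG2 (-0.82 ± 0.07), GDF15 (1.14 ± 0.07), SLC7A5 (1.29 ± 0.07), the lactate dehydrogenase LDHA (1.27 ± 0.06), TNFAIP2 (0.70 ± 0.08) and IRF9 (-1.29 ± 0.07) were examples. Of 12 housekeeping genes, 5 were higher, such as HPRT1 (1.36 ± 0.07) and TBP (0.82 ± 0.09), and 3 lower. Basal markers had FOXC1 higher (1.39 ± 0.12) and EGFR lower (-0.75 ± 0.09), fibroblast markers 1 higher and 2 lower of 9, and immune and endothelial markers 1 lower of 9. The lower fibroblast markers were FAP (-0.29) and COL1A2 (-0.26), which stand as low-signal references elsewhere in the text. Their calls ended under 5 and 7 of 19 alternatives, and that of CD3D, the lower immune marker, under 6 of 20. Beside these groups as well, the ACTB 3′ to 5′ gap was 1.76 against 0.68. In all, limma called 3379 genes higher and 3308 lower, 396 and 146 of them by at least 2-fold, or 42.0% of named genes. The even split depended on scaling, as 3775 were higher and 2797 lower with arrays centred on their medians, and 3186 and 3306 after quantile normalization.

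The EGF response itself was compared between the arrays with and without fulvestrant. Of the 607 genes that rose with EGF at 3 h, 238 were lower in the arrays labelled ICI and EGF than with EGF alone, 161 were higher and 208 did not pass. F2RL1 and MALL were among the first, and AREG among the second. A total of 393 of them were still called above control, and the median share of the rise that was left was 79.0%. Of the 601 genes that fell, 220 were higher with fulvestrant and EGF, 166 lower and 215 did not pass. PSCA and CCNG2 were among those lower still. Of these 601, 362 were still below control, and a median of 83.4% of the fall was left. In 100 simulations in which fulvestrant changed nothing, and almost no gene is called between these groups, 439 to 489 of 502 to 549 raised genes were still above control and 402 to 440 of 463 to 512 lowered genes still below it, with 96.1% to 99.7% of the rise and 94.0% to 99.8% of the fall left. In 100 further simulations, added after the counts were seen, the called differences with fulvestrant were given to other genes of like expression and spread. There 20.2% to 28.6% of raised genes were called lower, against 39.2% in the data, and the 26.5% called higher lay inside the simulated range. Of lowered genes, 24.1% to 32.5% were called higher, against 36.6%, and 17.9% to 27.5% lower, against 27.6%. These simulations called 2889 to 2994 genes lower in all, against 3308, and so somewhat too few. With no group on fulvestrant alone, these counts hold any effect it has without EGF, and the same arrays had the larger 3′ to 5′ gap of ACTB (1.76 against 0.68 at 3 h of EGF). The number raised and then higher was 103 without control replicate 1, 95 without EGF 3 h replicate 1 and 90 without EGF 3 h replicate 2. The number lowered and then higher was 110 and 106 without control replicates 1 and 2, and 92 and 103 without EGF 3 h replicates 1 and 2. The number lowered and then lower was 92 and 95 without control replicates 1 and 2, 78, 73 and 101 without EGF 3 h replicates 1, 2 and 3, and 253 with a variance trend and robust fit.

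**Figure D3:**
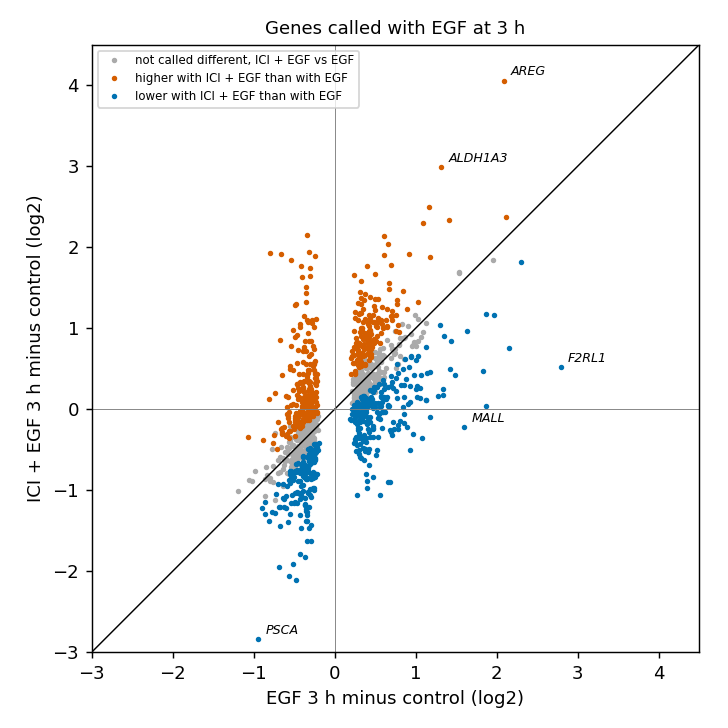
Each point is 1 of the 1208 named genes called in EGF 3 h against control. The horizontal axis is the log2 difference of EGF 3 h from control, the vertical axis that of the arrays labelled ICI and EGF from control, and the line marks equal values. Blue points (lower with fulvestrant and EGF than with EGF) number 238 right of 0 and 166 left of it, and orange points (higher) 161 and 220.

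The arrays labelled ICI and EGF were also compared with control, to ask what was left of the EGF response together with any effect of fulvestrant. AREG rose from 2.80 ± 0.20 to 6.85 ± 0.15, or at least 16.6-fold (adjusted p = 3.5e-10), with its control value again level with that of FAP (2.79). H4C3 (3.75 ± 0.12), CYP1B1 (3.39 ± 0.08), CYP1A1 (3.21 ± 0.14), the retinaldehyde dehydrogenase ALDH1A3 (2.99 ± 0.19), GAL (2.49 ± 0.14), CENPW (2.47 ± 0.07) and KIF15 (2.43 ± 0.14) were the next largest rises. The largest falls were in PSCA (-2.84 ± 0.11), RNASE4 (-2.37 ± 0.13), YPEL3 (-2.11 ± 0.06), RAB29 (-2.06 ± 0.13), PLEKHB1 (-2.03 ± 0.08), P2RX4 (-2.00 ± 0.11), CCNG2 (-1.95 ± 0.08) and the growth factor-binding protein IGFBP5 (-1.95 ± 0.12). All 29 measured genes of G1/S and replication and all 25 of G2/M and mitosis rose, also when adjusted over the list alone, with medians of 1.32 and 1.30 (camera adjusted p = 5.12e-22 for each). Ribosome biogenesis had 19 higher of 24 (median 0.66, camera adjusted p = 9.31e-11), FOXO and growth arrest 17 lower of 21 (median -0.79, camera adjusted p = 1.51e-10), luminal genes 12 lower of 16 (median -0.38, camera adjusted p = 9.11e-06) and estrogen-repressed genes 9 lower of 10 (median -1.11, camera adjusted p = 8.92e-08), and adjusted over the list alone these counts were 19, 18, 12 and 9. These calls held with an estimated correlation, and all were made on arrays with the larger ACTB 3′ to 5′ gap (1.76 against 0.81 in control).

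In the same comparison of the arrays labelled ICI and EGF with control, MAP kinase feedback genes had 10 higher and 4 lower of 24 (11 and 4 adjusted over the list alone), with PHLDA1 at 1.84 ± 0.07. Their median was 0.17 (camera adjusted p = 0.0137), with adjusted p = 0.159 by an estimated correlation and 0.0848 without the dimmest features. Estrogen-induced genes had 15 higher and 4 lower of 36 (15 and 5 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00354), but adjusted p = 0.122 with an estimated correlation and 0.0596 without the dimmest features. Cholesterol synthesis had 14 higher and 3 lower of 22 (14 and 5 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.000499, and adjusted p = 0.159 with an estimated correlation). Camera called none of the immediate early (13 higher, 9 lower of 29), EGF ligand and receptor (3 and 5 of 12), glycolysis (4 and 6 of 17), NF-κB (4 and 1 of 20), invasion (6 and 3 of 25), p53 (4 and 8 of 22), ATF4 (7 and 4 of 16), interferon (2 and 5 of 13), housekeeping (5 and 3 of 12), basal (2 and 1 of 8), fibroblast (1 and 2 of 9) and immune and endothelial (0 and 1 of 9) lists. EGR1 (1.69 ± 0.08), LAMB3 (1.21 ± 0.12), SLC7A5 (1.90 ± 0.07), EGLN3 (1.68 ± 0.14), IRF9 (-1.63 ± 0.07) and BTG2 (-1.39 ± 0.07) were examples from them. The 3′ to 5′ gap of ACTB was 1.76 on the arrays with these differences and 0.81 in control. In all, limma called 3447 genes higher and 3417 lower than in control, 420 and 193 of them by at least 2-fold. With arrays centred on their medians the numbers were 3742 and 3060, and after quantile normalization 3338 and 3443.

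The panel of 12 genes fixed beforehand holds ERα itself, classic targets of it and genes of EGF signalling. ESR1 was 6.51 ± 0.06 in control, 6.33 ± 0.04 at 3 h of EGF, 6.06 ± 0.09 at 12 h and 5.70 ± 0.06 in the arrays labelled ICI and EGF. The fall at 12 h (adjusted p = 0.00034) and that with fulvestrant and EGF against EGF 3 h (adjusted p = 6.87e-06) passed, and the difference at 3 h did not (adjusted p = 0.145). TFF1, a secreted protein induced by estrogen, was 11.63 ± 0.04, 11.72 ± 0.02, 11.84 ± 0.06 and 12.32 ± 0.03 in the same order, higher with fulvestrant and EGF than with EGF 3 h (adjusted p = 2.85e-06). GREB1 was 4.41 ± 0.11, 3.96 ± 0.14, 3.31 ± 0.18 and 5.12 ± 0.27, lower at 12 h than in control (adjusted p = 7.26e-05) and higher with fulvestrant and EGF than with EGF 3 h (adjusted p = 1.37e-05), where 1 other probe set of the gene was called lower. PGR, the progesterone receptor, stayed near the low end of the scale, at 2.22 ± 0.08, 2.34 ± 0.17, 2.32 ± 0.23 and 2.50 ± 0.28, and passed in none of the 5 comparisons. The receptor genes EGFR (5.15 ± 0.06, 5.40 ± 0.07, 5.08 ± 0.20 and 4.65 ± 0.05) and ERBB2 (6.49 ± 0.01, 6.33 ± 0.05, 6.21 ± 0.02 and 5.68 ± 0.09) were both lower with fulvestrant and EGF than with EGF 3 h (adjusted p = 2.07e-05 and 2.02e-06). For EGFR at 12 h against control 1 other probe set was called in the opposite direction. Its fall in the arrays labelled ICI and EGF against control (-0.50) depended on the probe set chosen. With the mean of the gene's probe sets it was -0.10 (limma adjusted p = 0.233). Cyclin D1, CCND1, rose from 8.17 ± 0.08 to 8.74 ± 0.05 at 3 h and 9.41 ± 0.04 at 12 h, and was 8.39 ± 0.10 with fulvestrant and EGF, lower than with EGF 3 h (adjusted p = 0.00103). MYC was 6.57 ± 0.06, 6.80 ± 0.05, 7.38 ± 0.01 and 6.61 ± 0.15, with a rise at 12 h (adjusted p = 1.02e-05). FOS was 4.32 ± 0.17, 4.77 ± 0.20, 5.52 ± 0.12 and 3.76 ± 0.39, and DUSP6 2.89 ± 0.17, 3.44 ± 0.02, 4.43 ± 0.23 and 3.57 ± 0.10. EGR1 was 4.56 ± 0.10, 6.09 ± 0.12, 7.42 ± 0.11 and 6.25 ± 0.04, and AREG 2.80 ± 0.20, 4.88 ± 0.19, 6.61 ± 0.09 and 6.85 ± 0.15. The arrays of the last group were those with the larger 3′ to 5′ gap of the ACTB control probe sets, which was not measured for the panel genes.

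**Figure D4:**
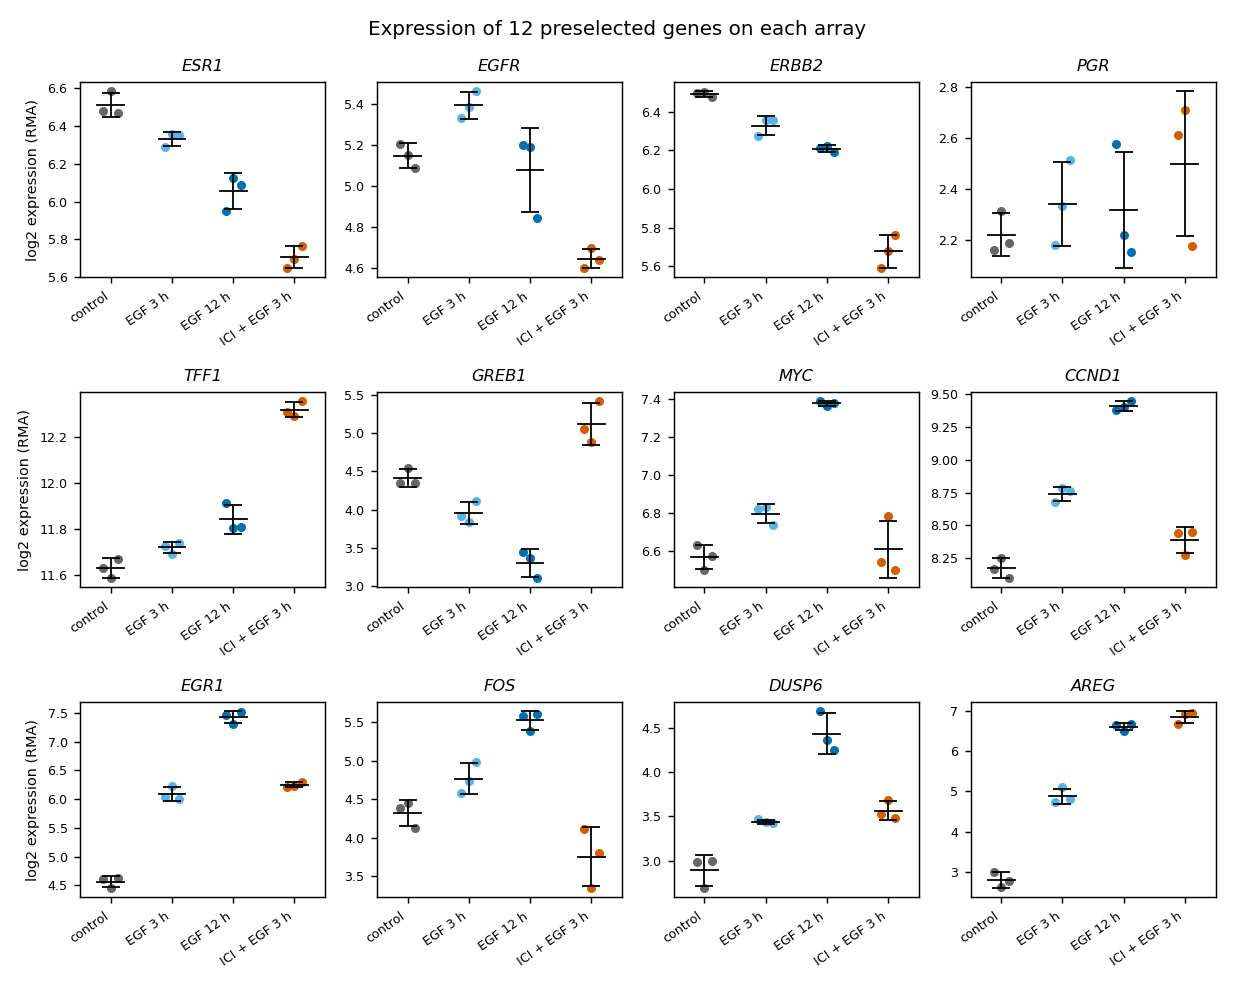
Log2 RMA signal of the 12 panel genes on each array (vertical axes, log2, with a range of their own for each gene). Points are arrays, and bars are the mean and SD of a group (n = 3). TFF1 is highest in the arrays labelled ICI and EGF, at 12.32, where ESR1 is lowest, at 5.70.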

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

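The tests of exchanged arrays, of a few genes, of 3′ bias, of a batch, of ERα loss and of differences unrelated to EGF below were chosen after the results they concern were seen, and those of selection and the splits of the arrays before.

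The response to EGF differed between its time points, by the limma test of 12 h against 3 h, in 931 genes that were higher at 12 h and 535 that were lower. List medians of this difference were 0.21 for immediate early genes, 0.68 for G1/S and replication, -0.26 for G2/M and mitosis, 0.22 for ribosome biogenesis, 0.21 for cholesterol synthesis and -0.15 for FOXO and growth arrest genes, where the calls of G2/M and of cholesterol synthesis were lost with an estimated correlation (adjusted p = 0.072 for each). Genes flagged by the same difference were KLK6 (2.07), H19 (1.98), AREG (1.73), CDCA7 (1.70), GPER1 (-1.39), RGCC (-1.15), DST (-1.15), SYBU (-1.08), GREB1 (-0.65), MYC (0.58), CCND1 (0.67), EGR1 (1.33), DUSP6 (0.99), FOS (0.75), ESR1 (-0.28) and EGFR (-0.32). The call of FOS ended without EGF 3 h replicate 1 (adjusted p = 0.063), EGF 12 h replicate 1 (0.0507) or EGF 12 h replicate 3 (0.0529), and that of ESR1 without EGF 3 h replicate 2 (0.0745), EGF 3 h replicate 3 (0.0711) or EGF 12 h replicate 1 (0.0905). The call of EGFR ended under 15 of 21 alternatives, with adjusted p up to 0.394. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as the real 1466, the real split itself, and the highest other gave 0.

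The same count of splits was 1 of 10 for each comparison. The real values were 1208 (EGF 3 h against control), 3173 (EGF 12 h against control), 6687 (arrays labelled ICI and EGF against EGF 3 h) and 6864 (the same against control), and the highest other was 0 for each. With 10 splits no share under 0.05 can be reached.

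Control probe sets, which no comparison of genes uses, set the arrays labelled ICI and EGF apart from the other 9. They were higher in the 3′ minus 5′ difference of ACTB (by 1.03), GAPDH (0.75) and STAT1 (0.54) and in 18S (2.04) and 28S (0.72) ribosomal RNA. Hybridization spikes were higher on average (0.29) but did not separate these arrays. EGF 12 h replicate 3, at 10.09, lay above replicates 2 and 3 of the arrays labelled ICI and EGF (10.07 each). The exact permutation test gave p = 0.00455 for the first 5 and p = 0.0364 for the spikes, and p = 0.00545 and 0.0364 after adjustment over the 6.

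On the arrays labelled ICI and EGF, the 54 cell cycle genes were higher than at 3 h of EGF by a median of 1.44. A 3′ bias of the RNA stays open for them, since normalization holds the medians of random lists near 0 (10000 lists matched on mean expression gave at most 0.27) and no transcript lengths were at hand to match them on. Loss of ERα activity would raise estrogen-repressed genes only where estrogen was repressing them, and their median was -0.50. EGF alone lowered this list too (median -0.59 at 3 h against control), and no group had fulvestrant alone. The median therefore does not exclude such a loss. Among other genes with 2 called probe sets, 18 of 311, or 5.79%, had probe sets going in opposite directions. At 12 h of EGF against control it was 1 of 123 (Fisher's exact p = 0.0192 between these shares), and at 3 h 1 of 36. A 3′ bias may have contributed to those calls, but far more named genes were called here (42.0%) than at 12 h (19.9%). Genes are not independent replicates, and the same genes can enter both shares. The Fisher p-value therefore does not measure the spread between arrays. A separate culture or array batch cannot be told apart from the treatment, since 0 arrays of other groups lay in the ACTB range of these 3, and other actions of fulvestrant were not tested.

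Immediate early genes, known for a response within the first hour, were higher at 12 h of EGF than at 3 h. An exchange of the 3 h and 12 h arrays would put the replication genes up in the arrays labelled 3 h, where their median was -0.12. A few genes do not carry the list, since 13 of its 29 members were called higher at 12 h. A second wave of signalling, for which the higher AREG offers a hypothesis, was not tested. On the arrays labelled ICI and EGF, AREG was higher still (6.85 against 6.61 at 12 h). There, 10 immediate early genes were lower and 3 higher than at 3 h of EGF, but those arrays also differ in treatment and RNA quality.

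Of the genes raised by EGF at 3 h, 238 were lower in the arrays labelled ICI and EGF. Selection on the EGF 3 h arrays, which both comparisons share, stays open as a part of this, since simulations without any effect of fulvestrant call almost no gene between these groups and so set no bound. With the called differences given to other genes, at most 28.6% of raised genes were called lower, against 39.2%. These simulations called somewhat too few genes lower in all (2889 to 2994, against 3308), and as a simulated bound this excludes nothing. Of the 466 genes called higher at both EGF times, 158 were lower and 153 higher, and of the 1565 called higher at 12 h 270 were lower and 783 higher; the 466 too were chosen partly on the EGF 3 h arrays. With no arrays of fulvestrant alone, an effect on the EGF response cannot be separated from an effect without EGF, nor from the RNA quality of these arrays.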

How the results depend on the processing

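The alternative without the arrays labelled ICI and EGF was chosen after the results were seen, and all others were planned. No result reversed. Of 338 called values of named genes 28 lost their call under some alternative, 27 of them with 1 array left out, and of 42 list calls 10 did. Lists that camera did not call depended on these choices too. Over the 5 comparisons fry called 26 of them and left 37 uncalled. With all probe sets as separate features, camera called 5 more. One was the immediate early list in the arrays labelled ICI and EGF against EGF 3 h (adjusted p = 0.0456). The genes lowered by EGF and then lower with fulvestrant numbered 253 with a variance trend and robust fit, against 166. Genes called in opposite directions at 3 h and 12 h of EGF numbered 20 with that fit, 21 without the dimmest features, 22 with all probe sets and 5 with only the 6 arrays compared, against 13. The cause was not tested, apart from the fewer or more features and arrays that these settings use.

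Leaving out each array in turn gave 404 to 636 genes higher and 309 to 659 lower at 3 h of EGF, and 561 to 998 higher and 308 to 602 lower at 12 h than at 3 h. Genes raised and then higher with fulvestrant ranged from 90 to 164, lowered and then higher from 92 to 254, lowered and then lower from 73 to 167, lower at both EGF times from 236 to 469, and opposite from 4 to 14. Fewer arrays in a group lower the power.

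With a replicate block, genes higher and lower numbered 508 and 461 (EGF 3 h), 1448 and 1460 (EGF 12 h), 3263 and 3175 (fulvestrant and EGF against EGF 3 h), 3335 and 3263 (against control) and 784 and 443 (12 h against 3 h). The block changed no count by over 1.5 times. Only 1 of 12 arrays correlated best with those of its own number.

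Without the arrays labelled ICI and EGF, genes higher and lower numbered 677 and 710 at 3 h of EGF, 1699 and 1808 at 12 h, and 1057 and 665 between them. The share of calls that were higher at 12 h than at 3 h was 63.5% as reported, 55.4% after quantile normalization and 67.7% with arrays centred on their medians. For the arrays labelled ICI and EGF it was 50.5%, 49.1% and 57.4% against EGF 3 h. Without calls of presence, differences from values near the 2.79 of FAP or the 3.05 of COL1A2 in control are at best lower bounds. Examples are those of DUSP6 (2.89 in control) and SHCBP1 (2.81 at 3 h of EGF). Changes of 0.5 were recovered for 78 of 100 simulated features. That simulation changed far fewer features than were called in any comparison here, so that its adjusted threshold was stricter. Its recovery therefore does not measure how often changes are missed in these data. The median absolute log2 difference of called genes ran from 0.36 (12 h against 3 h of EGF) to 0.43 (arrays labelled ICI and EGF against control). Small changes can still be missed, at a rate that was not measured.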

Other observations

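The gene families below, grouped by symbol, and the tests of S phase and of growth with estrogen were chosen after the results were seen.

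Of 221 families of at least 10 genes, those of mitochondrial ribosomal proteins had the smallest camera p-values in the arrays labelled ICI and EGF against EGF 3 h. Other families had larger median differences, such as MCM (1.07) and NDUFB (0.79). Of 49 MRPL genes, which encode the large mitochondrial subunit, 34 were higher and 4 lower, with a median of 0.50 (camera adjusted p = 1.37e-09, and adjusted p = 0.181 with an estimated correlation). Of 28 MRPS genes, of the small subunit, 21 were higher (median 0.41, camera adjusted p = 9.78e-08, and adjusted p = 0.158 with an estimated correlation). Proteasome genes (PSMB) had 9 of 10 higher with a median of 0.73, and the respiratory complex I genes of the NDUFA family 10 of 12 with a median of 0.72 (adjusted p = 0.291 for each with an estimated correlation). The 3′ to 5′ gap of ACTB was 1.76 on the same arrays against 0.68 at 3 h of EGF.

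At 12 h of EGF, 7 of 10 MCM genes, most of which encode the replicative helicase, were higher than at 3 h, with a median of 0.84 (camera adjusted p = 3.02e-11, and adjusted p = 0.0171 with an estimated correlation). Against control 7 of the 10 were also higher, with a median of 0.88. That call was lost with an estimated correlation (camera adjusted p = 3.64e-07, then 0.0703). All 12 PCDHGA protocadherin genes, which share exons, were lower at 12 h than in control, with a median of -0.30 (camera adjusted p = 1.42e-05, and adjusted p = 0.643 with an estimated correlation).

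A larger share of cells in S phase, as a hypothesis for the cell cycle genes in the arrays labelled ICI and EGF, would raise replication-dependent histone genes. The 44 measured had a median of -0.037, with 9 higher and 12 lower, and at 12 h of EGF 0 were higher and 13 lower by limma, so that members going both ways left this open. Many histone transcripts lack a poly(A) tail, and their labelling is not described.

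Growth with estrogen at the time of harvest was a further hypothesis for the arrays labelled ICI and EGF. It would raise estrogen-induced genes and G1/S genes and lower estrogen-repressed genes against control. The estrogen-repressed list had 9 of 10 members lower, with a median of -1.11 (adjusted p = 0.00399 with an estimated correlation), and all 29 measured G1/S genes were higher. The estrogen-induced list had 15 higher and 4 lower of 36, with a median of 0.12 and a call that was lost with an estimated correlation (adjusted p = 0.122). No array of estrogen-treated cells was there to compare, and the hypothesis stayed open.

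Activation of the aryl hydrocarbon receptor was considered for CYP1A1 and CYP1B1. Of 6 other listed targets, 2 were called higher than at 3 h of EGF, TIPARP (0.80) and UGT1A6 (0.26), while NQO1 was lower (-0.23), which left the hypothesis open. With EGF alone, UGT1A6 (0.27) and CYP1B1 (0.99) were higher at 12 h than at 3 h, while CYP1A1 did not pass (-0.11). Against control at 12 h, CYP1B1 was higher (0.99), but UGT1A6 did not pass (0.16, limma adjusted p = 0.0803). Of 17 genes of the UGT family, 10 were higher and 1 lower in the arrays labelled ICI and EGF than at 3 h of EGF.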
